A study of Mus musculus with 2 samples.

How the data were processed

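Chromatin immunoprecipitation with sequencing (ChIP-seq) for H3K4me3, the trimethylated form of histone H3 found at active and poised promoters, was carried out on hearts of mouse embryos of strain B6NCrl at embryonic day 16.5. Per the labels, male and female embryos were pooled, the library size range was 300 to 500 bp, and there were 2 biological replicates. Replicate 2 came from 41 hearts, and the number of hearts in replicate 1 was not given in the sources used here. Both replicates belong to 1 group, so the design holds no contrast between conditions, and comparisons were made between the replicates, between genomic locations and between groups of genes.

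The deposited files are lists of peaks in narrowPeak layout on genome build mm10. Per the labels and the text files deposited with them, 1 list was made from the alignments of replicate 1, 1 from those of replicate 2 and 1 from both pooled, each together with 1 or 2 further files whose kind is not named. The replicated list was derived from those 3 lists, and its peaks were checked to be an exact subset of the pooled list. The authors' signal value per peak is the caller's measure of enrichment, and what it is relative to is not given in the sources used here. The deposited −log10 p and −log10 q values per peak start at a −log10 p of about 2.00, so the lists include weak peaks, among them 332 of the replicated list with a q above 0.05. Aligner, peak caller and their versions are not given in the sources used here. Read depth is unknown, so precision was judged from the spread between the replicates (SD, n = 2). Signal values were used to describe and rank peaks within a list.

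Peaks on chromosomes 1 to 19, X and Y were used, with the GRCm38 genome and the GENCODE vM21 gene annotation, which hold 21938 protein-coding genes, 10155 lncRNA genes and 13523 pseudogenes on these chromosomes. A promoter was the region within 1000 bp of any annotated transcription start site (TSS). A peak was assigned to a promoter, otherwise an exon, otherwise an intron, otherwise to intergenic sequence. Peaks 1000 bp or less apart were joined into domains. A gene was marked if a peak reached its promoter, its domain was the widest that did so, and its signal was the highest signal value among the peaks at the promoter. Genes that share a domain share its width, and each annotated TSS was treated alike whether or not it is used in heart. Broad domains were the widest 5% of promoter domains, and distal domains lay over 5000 bp from every annotated TSS.

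A set of 32 gene lists was fixed before the data were examined, with the tests, most alternatives and the rule for named genes. The lists cover the heart muscle (cardiac transcription factors, sarcomere, calcium and ion handling, atrial, ventricular, conduction system), the other cells of the heart (endothelium and endocardium, lymphatic endothelium, fibroblast and epicardium, smooth muscle and pericyte, erythroid, macrophage and immune, neural crest and Schwann), other tissues (neuronal, hepatocyte, skeletal muscle only, lung epithelium, skin and keratin, photoreceptor, pancreas, germline), developmental groups (pluripotency, neural transcription factors, Hox genes, signalling ligands and receptors, extracellular matrix and valve, imprinted genes), and housekeeping or reference groups (cell cycle, glycolysis, fatty acid oxidation, ribosomal proteins, olfactory receptors). Of the symbols written, 5 were not found among protein-coding genes, 4 of them noncoding imprinted genes that are reported separately. Genes named are 11 heart genes chosen beforehand, those of the 20 widest promoter domains and of the 10 highest signals, the 3 widest and up to 3 unmarked members of each list, the 5 widest distal domains, and the 5 highest promoters marked in each replicate only. Any other gene was chosen after its values were seen.

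The share of marked members was compared with all other protein-coding genes by Fisher's exact test, two-sided. Odds ratios have 0.5 added to each cell of the table. Median width and median signal of the marked members were compared with 100000 random draws of as many marked protein-coding genes by a two-sided permutation test, whose smallest p is 2e-05. Only the 26 lists with at least 5 marked members entered those tests. P-values were adjusted by the Benjamini-Hochberg method over the lists of each measure, with a threshold of 0.05. Genes are the units of these tests, so the p-values describe gene lists in these libraries and not the spread between embryos. The union of the heart muscle lists was compared with the union of the neuronal, hepatocyte, skeletal muscle, skin, photoreceptor, pancreas and germline lists, and the atrial with the ventricular list by an exact permutation test. Chance overlap and location were estimated by placing each peak at random on its chromosome 100 times. The 95% intervals of shares are exact binomial ones and cover counting error only.

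The alternatives were each replicate's list alone, the pooled list, peaks with a −log10 q of 10 or more, peaks above the median signal, promoter flanks of 500 and 2500 bp, no joining or joining at 3000 bp, the most upstream TSS only, a reciprocal overlap of 50%, equal numbers of peaks, peaks wider than 200 bp, other summaries of signal, and matching of genes on 10 classes of the promoter ratio of observed to expected CpG dinucleotides. Widths from draws matched on the number of annotated TSSs (10 or more as 1 class), widths with 1 gene per domain, and signals matched on CpG ratio were added after the data were seen. The CpG ratio was taken over 500 bp on each side of a TSS, and a gene took the highest value of its TSSs. The CpG-matched test of marked shares is a Mantel-Haenszel odds ratio with 0.5 spread over the cells of the list and an exact p. It took this form after a first version with a chi-square p and no addition, which gave no finite odds ratio for lists with every member marked, had been seen.

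The width and share tests were tested on simulated data, in 200 lists of 20 genes per setting. Among 14933 marked genes, a planted width fold of 1.5 was called in 87.5% of lists, a fold of 2 in 100% and a fold of 1 in 4.5%. Among 21938 protein-coding genes, lists with 95% of members marked were called in 87.5%, lists with 35% in 86.5%, and lists at the share of all genes in 3% of cases. A call in the simulation used the p-value of each list without adjustment over lists. These rates are therefore not those of the adjusted calls reported below. Lists with fewer marked members, such as skin and keratin with 5, were not simulated. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Peaks on unlocalized and unplaced scaffolds were left out of all comparisons.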

Results

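H3K4me3 was mapped in the embryonic mouse heart at day 16.5 in 2 biological replicates, each a pool of hearts from male and female embryos. The replicate lists hold 35066 and 30300 peaks, a mean of 32683 ± 3370.1 (SD, n = 2), and the pooled and replicated lists 32740 and 29778. Median peak width was 748.5 bp in replicate 1 and 862 bp in replicate 2, and peaks covered 36.6 ± 3.53 Mb (SD, n = 2), or 1.34% ± 0.129 of the genome. Read depth is unknown. Values below are from the replicated list unless a replicate is named, and a value with an SD is the mean of the 2 replicates.

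The widest H3K4me3 domains of the genome's promoters lay over transcription factors that build the heart. The domain of Nkx2-5, a homeodomain factor of the cardiac lineage, ranked first among 13415 promoter domains, at 18583 bp (chromosome 17, 26835846 to 26854428), and contained the whole gene. Its width was 18400.5 ± 163 bp in the replicates taken alone (SD, n = 2). The zinc finger factor Gata4 followed with 18214 bp (chromosome 14, 63234858 to 63253071; 17453.5 ± 886 bp, SD, n = 2), and the basic helix-loop-helix factor Hand2 with 17935 bp (chromosome 8, 57311725 to 57329659). The Hand2 domain differed between the replicates, at 23358 bp in replicate 1, where it was wider than that of Nkx2-5, and 12582 bp in replicate 2. The T-box factors Tbx20 and Tbx5 had domains of 15393 bp (14606.5 ± 1228 bp, SD, n = 2) and 12954 bp (12636.5 ± 412 bp, SD, n = 2), and Gata6 one of 14026 bp (13783.5 ± 114 bp, SD, n = 2).

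Genes of the contractile apparatus carried wide domains as well. Myh7, which encodes the beta-myosin heavy chain of the fetal ventricle, had a domain of 17838 bp on chromosome 14 (54980081 to 54997918) that covered 60.8% of the gene, with 15250.5 ± 262 bp in the replicates (SD, n = 2). Myh7 shared this domain with the antisense noncoding gene Gm31251, which starts at 54979393, and its widest single peak was 13453 bp. Its neighbour Myh6, the alpha-myosin heavy chain, had a separate domain of 10123 bp (54957801 to 54967923; 10262.5 ± 185 bp, SD, n = 2) that covered 36.5% of the gene. Cardiac actin, Actc1, had 10657 bp (10533 ± 257 bp, SD, n = 2) over 94.8% of the gene, and cardiac troponin T, Tnnt2, had 7240 bp (7550 ± 587 bp, SD, n = 2). The natriuretic peptide genes were marked more narrowly. Nppb had a domain of 2720 bp with a signal of 17.6 ± 5.37 (SD, n = 2), and Nppa, the gene of the atrial peptide, one of 1926 bp with a signal of 4.15 ± 1.90 (SD, n = 2), below the median signal of all marked protein-coding genes in either replicate (40.0 and 34.8).

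**Figure D1:**
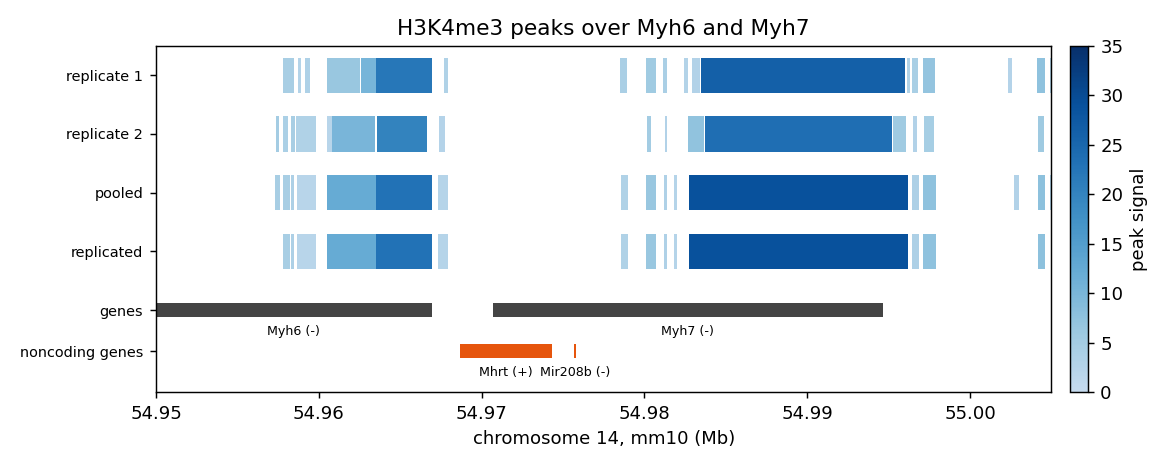
Peaks of each list over Myh6 and Myh7 on chromosome 14 of mm10 (position in Mb), shaded by the authors' signal value, with the genes and the noncoding genes Mhrt and Mir208b below and their strands in parentheses. In all lists the Myh7 peaks are widest over the 5′ part of the gene, and a gap without peaks separates them from those of Myh6.

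Besides Myh7 and the 6 transcription factors above, the 20 widest promoter domains included further regulators. Meis2 (16810 bp) and Meis1 (14303 bp) encode homeodomain cofactors, Nfib (16731 bp) a nuclear factor I protein, Tbx2 (15718 bp) a T-box repressor and Irx5 (14262 bp) an Iroquois factor. Kdm6b (13019 bp) and Setd1b (13420 bp, shared with Rhof) encode a histone demethylase and a histone methyltransferase, and Igf2 (12101 bp) and Irs1 (10850 bp) belong to insulin-like growth factor signalling. Bahcc1 (12022 bp), Tnrc18 (11604 bp), Pcdh7 (11349 bp) and the pair 1110002E22Rik and Gm5105 (11013 bp) completed the set. The Kdm6b domain was 6888 and 6966 bp in the single replicates, that of Tbx2 15739 and 9298 bp and that of Meis1 14238 and 9550 bp. The domain shared by Setd1b and Rhof was 13492 bp in replicate 1, and in replicate 2 they had separate domains of 10514 and 963 bp.

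Every member of the lists of cardiac transcription factors (18 of 18), sarcomere (24 of 24), calcium and ion handling (16 of 16) and atrial genes (11 of 11) was marked, against 68.1% of protein-coding genes overall. Adjusted p was 0.00346, 0.000720, 0.00551 and 0.0338 by two-sided Fisher's exact test, with odds ratios of 17.4, 23.0, 15.5 and 10.8. The ventricular list was marked in 9 of 9 members (odds ratio 8.92, adjusted exact p = 0.0779 by Fisher's exact test) and the conduction system list in 13 of 14 (odds ratio 4.23, adjusted exact p = 0.0617), neither past the threshold. The exception was Cntn2, a cell adhesion gene of conduction cells. With genes matched on promoter CpG ratio, the transcription factors' odds ratio was 2.496 and no longer passed, while those of sarcomere (54.6), calcium (14.3) and atrial genes (14.3) still did, and that of conduction genes turned to 0.144 without passing. The atrial share no longer passed with stricter peaks, a 500 bp flank or the most upstream TSS only (odds ratios 1.97, 3.37 and 3.88), and turned with peaks above the median signal (0.780), where the ventricular (12.5) and conduction shares (5.94) passed.

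All 6 heart muscle lists were wider than other marked genes, whose median domain was 2045 bp. Cardiac transcription factors had a median of 6936.5 bp (6510.3 ± 788 bp in the replicates, SD, n = 2), 3.39 times that of random draws. Sarcomere genes had 6516 bp (5977.3 ± 740.0 bp, SD, n = 2; ratio 3.19) and ventricular genes 6268 bp (6447 ± 429.9 bp, SD, n = 2; ratio 3.07). For calcium and ion handling the median was 5522 bp (5345 ± 364 bp, SD, n = 2; ratio 2.70), with Gja1, the main gap junction gene of ventricular muscle, at 10013 bp, the sodium-calcium exchanger Slc8a1 at 9370 bp and phospholamban, Pln, at 9038 bp. Each of these 4 lists reached the smallest permutation p that the draws can give, 2e-05 (adjusted 5.2e-05). The atrial median was 3460 bp (ratio 1.69, adjusted permutation p = 0.00968), led by the nuclear receptors Nr2f1 (9609 bp) and Nr2f2 (8261 bp) and the left-side factor Pitx2 (5715 bp). The conduction median was 2993 bp (ratio 1.46, adjusted permutation p = 0.0323), led by the T-box genes Tbx2, Tbx3 (7413 bp) and Tbx18 (4685 bp). The order of the atrial leaders depended on the replicate, with Nr2f1 at 6982 and 9396 bp and Nr2f2 at 13270 and 8213 bp in replicates 1 and 2. The atrial call ended without replicate 1 (ratio 1.37), with peaks not joined (1.297) and above the median signal (1.51). The conduction call ended with CpG-matched draws (1.35) and with joining at 3000 bp (1.42).

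**Figure D2:**
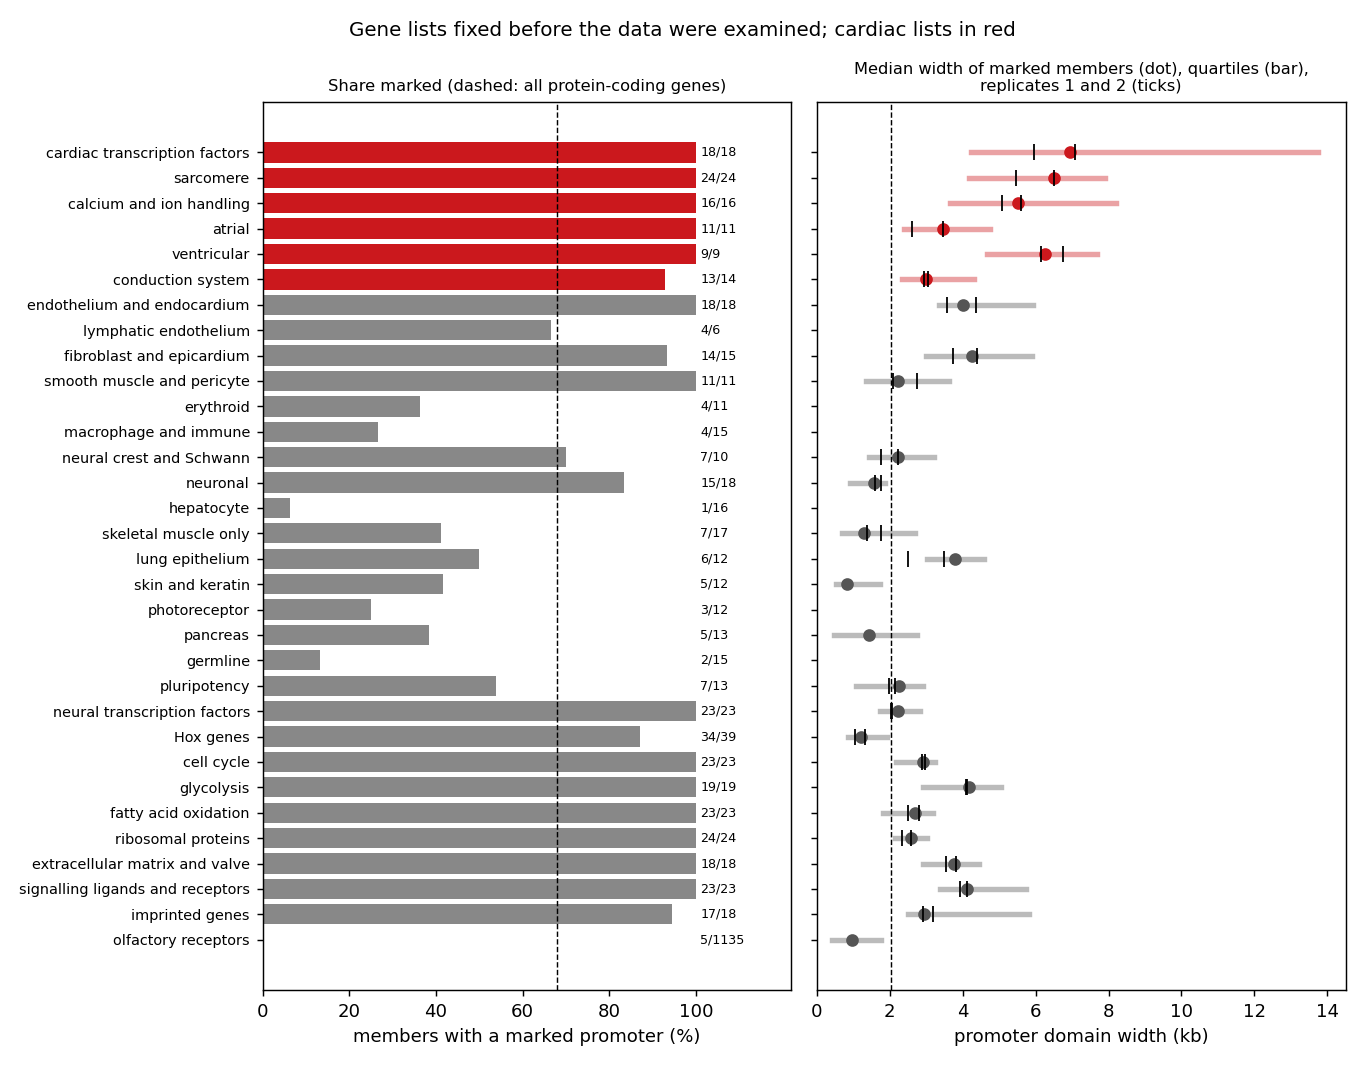
Share of members with a marked promoter (left, %, with marked and total members) and promoter domain width of the marked members (right, kb) for 32 gene lists, cardiac lists in red; dots are medians, bars quartiles, black ticks the medians of replicates 1 and 2, and dashed lines all protein-coding genes. Cardiac transcription factors have the widest median, 6936.5 bp, and 14 lists are marked in every member.

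Genes of endothelial, fibroblast and smooth muscle cells were nearly all marked too. All 18 genes of endothelium and endocardium were marked (odds ratio 17.4, adjusted exact p = 0.00346, Fisher's exact test), with a median width of 4000.5 bp (3966.3 ± 553 bp, SD, n = 2). The widest were Nfatc1, a factor of the endocardium and valves (9389 bp), Egfl7 (7336 bp, shared with Gm20532) and Notch1 (7032 bp). Nfatc1 had 9379 bp in replicate 1 and 5649 bp in replicate 2, where Egfl7 (6917 bp) and Notch1 (6695 bp) were wider. Fibroblast and epicardial genes had a median of 4259.5 bp (4066.3 ± 468 bp, SD, n = 2), with Pdgfra (8972 bp), the epicardial factor Wt1 (8326 bp) and Tcf21 (7209 bp). Both width calls had adjusted permutation p = 5.2e-05, from the smallest p possible. Of the fibroblast list, 14 of 15 were marked (odds ratio 4.54, adjusted exact p = 0.0617), and the mesothelial gene Upk3b was not. All 11 smooth muscle and pericyte genes were marked (odds ratio 10.8, adjusted exact p = 0.0338), led by Smtn (4998 bp), Cspg4 (4514 bp, shared with Odf3l1) and Pdgfrb (3963 bp), at a median width of 2217 bp that did not pass (ratio 1.08, adjusted permutation p = 0.665). The smooth muscle share no longer passed with stricter peaks (3.64), nor did the fibroblast width with peaks not joined (1.34). Above the median signal the endothelial (1.27) and smooth muscle shares (1.10) did not pass and the fibroblast share turned (0.748), while with CpG-matched genes the fibroblast share passed (7.57).

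Blood and immune genes were marked in few cases. Of macrophage and immune genes, 4 of 15 were marked (odds ratio 0.183, adjusted exact p = 0.00346, Fisher's exact test): the leukocyte antigen gene Ptprc (2530 bp), Laptm5 (2161 bp) and Cd3e (1152 bp) were the widest, and Adgre1, C1qa and C1qb were unmarked. In replicates 1 and 2 Ptprc had 1421 and 2512 bp, and Cd3e 750 and 1230 bp. Of erythroid genes, 4 of 11 were marked (odds ratio 0.281, adjusted exact p = 0.0617), with the erythropoietin receptor gene Epor at 2230 bp, Klf1 at 1726 bp and Gypa at 1139 bp. Alas2, Gata1 and the alpha-globin gene Hba-a1 were unmarked, and near-identical globin copies may escape peak calling, so their state is uncertain. Of lymphatic genes, 4 of 6 were marked (odds ratio 0.844, adjusted exact p = 1), among them Prox1 (8279 bp), Pdpn (3401 bp, with 3409 and 1342 bp in the replicates) and Reln (2185 bp), while Lyve1 and Ccl21a were not. Of neural crest and Schwann genes, 7 of 10 were marked (odds ratio 1.01, adjusted exact p = 1), with Tfap2a (5173 bp), Ednrb (4099 bp) and Foxd3 (2303 bp) widest and Phox2b, Plp1 and S100b unmarked, at a median of 2223 bp (ratio 1.09, adjusted permutation p = 0.683). With CpG-matched genes the macrophage (1.98) and erythroid odds ratios (2.43) both turned above 1, without passing, so the low shares of these lists were not separated from promoter CpG content. The neural crest share lay on either side of 1 over the settings (0.794 with CpG-matched genes), and the lymphatic one turned to 1.69 in the pooled list, neither passing.

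Genes of tissues that were not sampled were marked far less often than heart muscle genes. Of the heart muscle union, 86 of 87 genes were marked (98.9%), against 38 of 103 (36.9%) of the other-tissue union. The odds ratio was 98.1 (p = 2.48e-22, two-sided Fisher's exact test). Marked heart genes had a median width of 5284 bp and marked other-tissue genes 1291 bp, a difference of 3993 bp (two-sided permutation p = 2e-05, the smallest possible). In the single replicates the differences were 3918 and 3467 bp, and 2277.5 bp with peaks above the median signal. Among genes with a promoter CpG ratio of 0.6 or more, 51 of 51 against 21 of 26 were marked (p = 0.00333, Fisher's exact test), and below it 35 of 36 against 17 of 77 (p = 3.27e-15).

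Within the other tissues, hepatocyte genes had 1 marked member of 16 (odds ratio 0.0453, adjusted exact p = 6.5e-06, Fisher's exact test), the transferrin gene Trf at 872 bp in a domain shared with Gm20425, while Alb, Afp and Ahsg were unmarked. Afp had a weak domain of 1442 bp (signal 3.18) in replicate 1 only. Germline genes had 2 of 15 (odds ratio 0.0867, adjusted exact p = 0.000198), Dazl at 819 bp and Tex14 in a domain shared with Rad51c, with Ddx4, Mael and Oosp1 unmarked. Photoreceptor genes had 3 of 12 (odds ratio 0.173, adjusted exact p = 0.00551), Opn1sw, Nrl and Gnat1, and not Crx, Gnat2 or Nr2e3. Pancreas genes had 5 of 13 (odds ratio 0.303, adjusted exact p = 0.0486), with the developmental factors Nkx2-2 (3286 bp, with 3160 and 2121 bp in the replicates), Nkx6-1 (2733 bp) and Ptf1a (1423 bp) marked and Gcg, Cpa1 and Cela1 unmarked. Genes restricted to skeletal muscle had 7 of 17 (odds ratio 0.335, adjusted exact p = 0.0486), widest at the creatine kinase gene Ckm (4267 bp), which is also a heart gene, at Mylpf and at Actn3, whose domains were shared with Tbc1d10b and Zdhhc24. The skeletal actin gene Acta1, the myogenic factor Myf5 and Myh1 were unmarked. Only 5 of 1135 olfactory receptors were marked (odds ratio 0.00191), among them Olfr607 (1842 bp, with 1889 and 735 bp in the replicates), Olfr56 (1752 bp, shared with Ifi47 and not marked in replicate 2) and Olfr94 (957 bp), with Olfr1, Olfr10 and Olfr1000 unmarked, and their median width of 957 bp was 0.468 times that of draws (adjusted permutation p = 0.0179). With 4 and 3 marked members in replicates 1 and 2, that width was tested in neither replicate alone. Against CpG-matched draws that width ratio was 0.734 and did not pass. With CpG-matched genes the germline (0.0241) and olfactory (0.0278) odds ratios still passed, and those of hepatocyte (0.171), photoreceptor (0.321), pancreas (0.134) and skeletal muscle genes (0.624) did not. By the first form of that test, with a chi-square p, the hepatocyte and pancreas shares still passed below other genes, so these calls depend on its form. With the most upstream TSS only, the pancreas (0.358) and skeletal muscle shares (0.395) did not pass, nor did they with a flank of 500 bp (0.311) and of 2500 bp (0.401) respectively.

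In the remaining tissue lists the marked share did not pass the threshold. Neuronal genes had 15 of 18 marked (odds ratio 2.08, adjusted exact p = 0.239), with the GABA synthesis genes Gad1 (3127 bp) and Gad2 (2196 bp) and the factor Neurog2 (2582 bp) widest and Neurod6, Slc17a6 and Th unmarked, at a median of 1559 bp (ratio 0.762, adjusted permutation p = 0.0771). Lung epithelial genes had 6 of 12 (odds ratio 0.469, adjusted exact p = 0.239), and none of Napsa, Scgb1a1 and Sftpa1. In replicate 1 they had 8 of 12 (odds ratio 0.871), and that replicate alone marked Napsa (185 bp, signal 2.86) and Sftpc (3513 bp, signal 48.1). Replicate 2 had a domain 1140 bp from the start site of Sftpc, just outside the promoter limit. The widest lung genes of the replicated list were Id2 (8952 bp), Nkx2-1 (4621 bp, with 5609 and 2175 bp in the replicates) and Hopx (4502 bp). The lung list had a median of 3790.5 bp (ratio 1.84, adjusted permutation p = 0.0165), and Hopx is on the cardiac list as well. Without replicate 1 the lung width ratio was 1.301 and did not pass, as with peaks above the median signal (1.06), not joined (1.09) or joined at 3000 bp (1.74) and a flank of 2500 bp (1.48). Skin and keratin genes had 5 of 12 marked (odds ratio 0.344, adjusted exact p = 0.0778), Lor (1868 bp, not marked in replicate 2), Krt10 (1724 bp) and Krt1 (823 bp) widest and Dsg1a, Dsg3 and Flg unmarked, and were narrow at a median of 823 bp (ratio 0.403, adjusted permutation p = 0.00968). That width call ended with a flank of 2500 bp (0.665), joining at 3000 bp (0.801) and CpG-matched draws (0.559), and the skin share passed without replicate 1 (0.255) and turned to 1.25, without passing, with CpG-matched genes. The domains of Lor, Krt10 and Krt1 lay inside the genes, downstream of their 5′ ends. Krt10 and Krt1 were marked through annotated start sites within the gene, and Lor at the edge of the promoter limit. The narrow widths therefore need not describe the main promoters of skin genes. With CpG-matched genes the pluripotency share passed below other genes (0.156), and the neuronal share was 0.990, and with peaks above the median signal 0.343, past the threshold. Pluripotency genes had 7 of 13 (odds ratio 0.541, adjusted exact p = 0.396), with Klf4 (5121 bp), Sox2 (3004 bp) and Sall4 (2810 bp) widest and Nanog, Dppa4 and Dppa5a unmarked, at a median of 2262 bp (ratio 1.10, adjusted permutation p = 0.665). The widths of marked skeletal muscle (1285 bp, ratio 0.629, adjusted permutation p = 0.0522) and pancreas genes (1423 bp, ratio 0.696, adjusted permutation p = 0.172) did not pass.

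Neural transcription factors and Hox genes were mostly marked, but with low signal. All 23 neural transcription factors were marked (odds ratio 22.1, adjusted exact p = 0.000720, Fisher's exact test), led in width by Irx1 (6460 bp), the eye and brain factor Pax6 (4575 bp) and En2 (3873 bp, with 3724 and 2082 bp in the replicates), at a median of 2233 bp (ratio 1.09, adjusted permutation p = 0.524). Their median signal was 14.1, a ratio of 0.327 to draws of other marked genes (adjusted permutation p = 0.000520). Hox genes, which set position along the body axis, were marked in 34 of 39 members (odds ratio 2.95, adjusted exact p = 0.0174), with a median signal of 8.43 (ratio 0.195, adjusted permutation p = 0.000520, from the smallest p possible) and a median width of 1211 bp (1181.8 ± 181 bp, SD, n = 2; ratio 0.592, adjusted permutation p = 5.2e-05). Hoxa1 and Hoxa2 shared a domain of 8986 bp, Hoxb2 had 3518 bp, and Hoxb8, Hoxb13 and Hoxc11 were unmarked, although replicate 1 alone marked Hoxb8 (4209 bp, signal 4.52) and Hoxb13 (185 bp, signal 3.11). Without replicate 1, 29 of 39 Hox genes were marked and the call ended (odds ratio 1.36), with stricter peaks it turned (0.821), and above the median signal it lay below other genes past the threshold (0.299). Neither the Hox (0.403) nor the neural odds ratio (0.585) stayed above 1 with CpG-matched genes, and the neural one was 2.40 with the most upstream TSS only and 0.513 above the median signal, without passing.

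**Figure D3:**
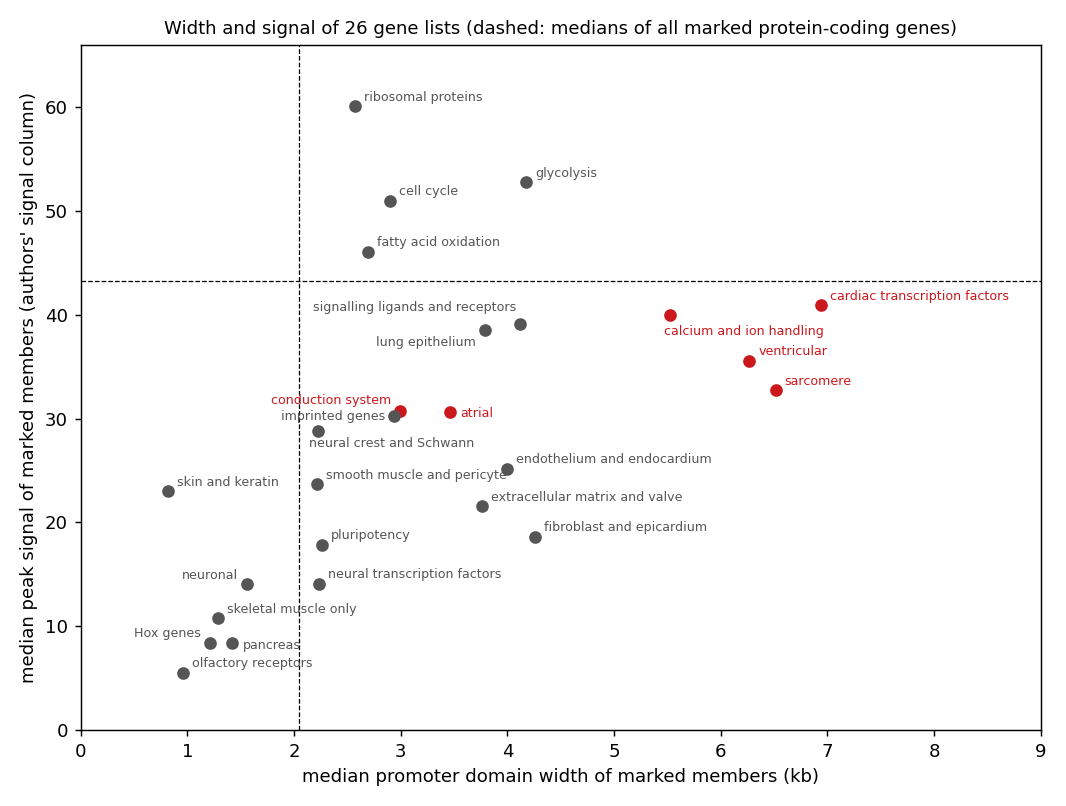
Median promoter domain width (kb) against median of the authors' signal value for the marked members of 26 gene lists, cardiac lists in red, with dashed lines at the medians of all marked protein-coding genes. Cardiac lists lie to the right and below the signal line without passing the threshold, ribosomal proteins highest in signal at 60.1, and Hox genes low in both.

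Metabolic and growth genes were all marked. Glycolysis genes (19 of 19, odds ratio 18.3, adjusted exact p = 0.00286, Fisher's exact test) had a median width of 4175 bp (4113.5 ± 19.1 bp, SD, n = 2; ratio 2.04, adjusted permutation p = 5.2e-05), led by the muscle enolase Eno3 (7283 bp, shared with Pfn1), Pkm (6792 bp) and Gapdh (6364 bp). Fatty acid oxidation genes (23 of 23, odds ratio 22.1, adjusted exact p = 0.000720) had 2691 bp (2651.5 ± 226 bp, SD, n = 2; ratio 1.31, adjusted permutation p = 0.0390), led by the nuclear receptor Esrrg (5671 bp), Cpt1a (5025 bp), the enzyme of mitochondrial fatty acid import, and Fabp3 (4699 bp, shared with Gm10570). Cell cycle genes (23 of 23, odds ratio 22.1, adjusted exact p = 0.000720) had 2904 bp (2919 ± 65.1 bp, SD, n = 2; ratio 1.42, adjusted permutation p = 0.00968), led by the cyclins Ccnd2 (7564 bp) and Ccnd1 (6539 bp) and by Mki67 (4385 bp). Ribosomal protein genes (24 of 24, odds ratio 23.0, adjusted exact p = 0.000720) had 2570 bp (ratio 1.26, adjusted permutation p = 0.0703), widest at Rps2 (5670 bp, shared with Ndufb10 and Rnf151), Rpl7 (4672 bp, shared with Rdh10) and Rpl3 (3579 bp). With CpG-matched genes the shares of glycolysis (4.08), cell cycle (0.835) and ribosomal genes (0.389) no longer passed, and that of fatty acid oxidation did (7.20). The width call of fatty acid oxidation ended with stricter peaks (1.25).

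Signalling, matrix and imprinted genes were also wider than other genes. Signalling ligands and receptors (23 of 23 marked, odds ratio 22.1, adjusted exact p = 0.000720, Fisher's exact test) had a median of 4118 bp (4015.5 ± 146 bp, SD, n = 2; ratio 2.01), with Igf2, Wnt5a (7963 bp) and Fgf9 (7411 bp) widest. Extracellular matrix and valve genes (18 of 18, odds ratio 17.4, adjusted exact p = 0.00346) had 3762 bp (3679.8 ± 193 bp, SD, n = 2; ratio 1.84), with Tbx20, the cartilage and valve factor Sox9 (5595 bp) and Col5a1 (4573 bp) widest. Both had adjusted permutation p = 5.2e-05 for width. Imprinted protein-coding genes (17 of 18, odds ratio 5.48, adjusted exact p = 0.0338) had 2936 bp (3046.5 ± 192 bp, SD, n = 2; ratio 1.44, adjusted permutation p = 0.0192), with Igf2, Grb10 (7407 bp) and Igf2r (6816 bp) widest and Ndn unmarked. The imprinted noncoding genes Airn (5385 bp), Kcnq1ot1 (3571 bp), H19 (3343 bp) and Meg3 (3067 bp) were marked in both replicates. With CpG-matched genes the shares of signalling (3.07), matrix (3.96) and imprinted genes (0.867) no longer passed, and neither did the imprinted share with the most upstream TSS only (2.45) or the imprinted width with peaks not joined (1.22).

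Width and signal did not rank the lists alike. The highest signals lay at other promoters than the widest domains. The shared promoter of Acad11 and Uba5 had 84.3 (71.2 ± 9.46 in the replicates, SD, n = 2). The chaperones Hsp90ab1 and Hspa4 had 83.0 (70.1 ± 3.72 in the replicates, SD, n = 2) and 80.6 (60.6 ± 17.6, SD, n = 2). The translation factor Eif4a2 had 80.4 (68.1 ± 1.61 in the replicates, SD, n = 2). The promoters of BC049715 and Wbp11, Mau2 and Sugp1, and Rnf10 followed. Ribosomal protein genes were the only list of 26 above other marked genes in signal (median 60.1, ratio 1.39, adjusted permutation p = 0.00143), and 11 lists were below. Those were, with their medians, Hox genes, neural transcription factors, neuronal (14.05), pancreas (8.38), skeletal muscle (10.8), olfactory receptor (5.53), fibroblast (18.6), extracellular matrix (21.6), endothelium (25.2), smooth muscle (23.7) and pluripotency genes (17.9), with ratios from 0.128 to 0.583. None of the heart muscle lists passed in the replicated list: the sarcomere median was 32.7 (ratio 0.757, adjusted permutation p = 0.0876) and that of cardiac transcription factors 40.9 (0.947, adjusted permutation p = 0.694). The medians of calcium (39.9), ventricular (35.6), conduction (30.7) and atrial genes (30.6) did not pass either. In replicate 2 alone the sarcomere median was 24.2 and passed as low (ratio 0.695, adjusted permutation p = 0.0394). Among the other lists that did not pass, glycolysis (52.8), cell cycle (51.0) and fatty acid oxidation genes (46.1) had medians above that of all marked genes (43.2), and signalling (39.1), lung (38.5), imprinted (30.2), neural crest (28.9) and skin genes (23.0) below it. The neural crest median was 27.4 in replicate 1 and 13.1 in replicate 2, where it passed as low (ratio 0.375), as did the imprinted one (27.3 and 19.1, ratio 0.549 in replicate 2), and the skeletal muscle median was 10.2 and 17.5. Against CpG-matched genes the sarcomere ratio turned to 1.83 and passed, the smooth muscle ratio turned to 1.09, and the endothelial (0.757), fibroblast (0.546), skeletal muscle (0.362) and olfactory ratios (0.417) no longer passed. The smooth muscle call ended in replicate 1 (0.608) and in replicate 2 (0.631) alone, and the matrix (0.675) and skeletal muscle calls (0.507) in replicate 2 alone.

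**Figure D4:**
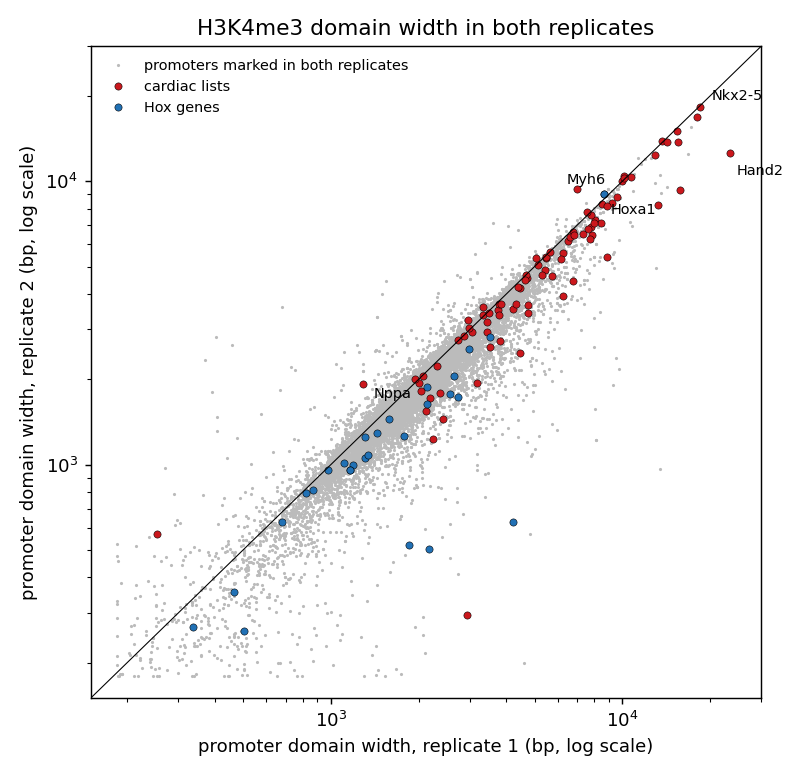
Promoter domain width in replicate 1 against replicate 2 (bp, log scales) for protein-coding promoters marked in both, with cardiac lists in red, Hox genes in blue and the line of equal width. Width was within 1.5-fold in 94.0% of promoters, and Hand2 was wider in replicate 1 (23358 against 12582 bp).

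Among the widest 5% of promoter domains, 671 domains above 4702 bp that held 777 protein-coding genes, 10 of the 26 lists were enriched. Sarcomere genes had 16 of 24 marked members there (66.7%, odds ratio 36.1, adjusted exact p = 3.21e-14, Fisher's exact test), ventricular genes 6 of 9 (odds ratio 34.1), calcium and ion handling 10 of 16 (odds ratio 29.8) and cardiac transcription factors 10 of 18 (odds ratio 22.8), against about 5.10 to 5.17% of other marked genes. Signalling (10 of 23, odds ratio 14.3), endothelial (7 of 18, odds ratio 12.0), imprinted (6 of 17, odds ratio 10.4), glycolysis (6 of 19, odds ratio 8.83), fibroblast (4 of 14, odds ratio 7.84) and atrial genes (3 of 11, odds ratio 7.52, adjusted exact p = 0.0440) were the others. The 16 lists that did not pass had at most 2 members each there, such as the conduction genes Tbx2 and Tbx3. The replicates alone put the threshold at 4826 and 4382 bp.

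Atrial genes had a narrower median domain than ventricular genes, which did not pass in the replicated list, the list fixed for this test. The difference passed in each replicate alone, over the same genes and without adjustment. The atrial median was 3460 bp and the ventricular one 6268 bp over 11 and 9 genes, a difference of -2808 bp (two-sided exact permutation p = 0.0821). In replicate 1 the difference was -3305 bp (exact permutation p = 0.0377) and in replicate 2 it was -3539 bp (exact permutation p = 0.0392). Irx5 and Myh7 gave the ventricular list its widest domains, while Nppa and Sln, a regulator of the calcium pump, had 1926 and 784 bp, the narrowest of the atrial list. The difference in median signal, 30.6 against 35.6, did not pass (difference -4.94, exact permutation p = 0.538). The width difference was -1783 bp with peaks above the median signal, where that in signal turned to 3.90, and -5567 bp with joining at 3000 bp, none of them passing.

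Of all replicated peaks, 62.6% (18640) lay at promoters and held 82.7% of the covered bases, against 9.53% (range 9.03 to 9.96) when peaks were placed at random. The shares in exons, introns and intergenic sequence were 5.51, 16.5 and 15.3%, against 8.23, 32.4 and 49.8% at random. Promoter peaks were 1597 bp wide with a median signal of 33.9, and intron peaks 424 bp with 4.37. The promoter share was 61.0% ± 5.46 in the single replicates (SD, n = 2). Protein-coding genes were marked in 68.1% of cases (14933 of 21938, interval 67.4 to 68.7%; 67.9% ± 0.709, SD, n = 2), lncRNA genes in 27.5% (27.3% ± 0.933, SD, n = 2) and pseudogenes in 2.80% (2.81% ± 0.256, SD, n = 2). These differences exceed the spread between the replicates many times. The gene types were not matched on their number of annotated start sites or on promoters shared with other genes.

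**Figure D5:**
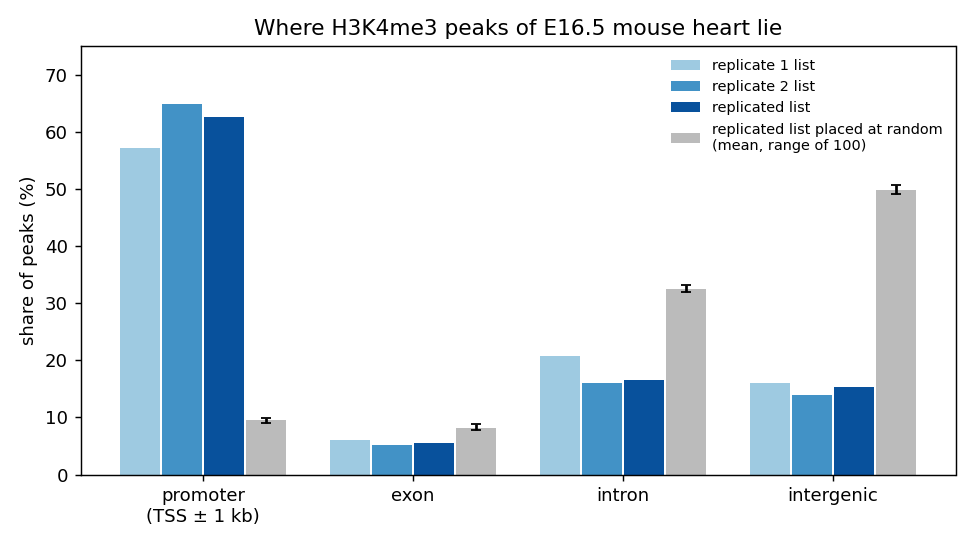
Share of peaks (%) at promoters, exons, introns and intergenic sequence for replicate 1, replicate 2 and the replicated list, and for replicated peaks placed at random (grey, mean with the range of 100 placements). Promoters hold 62.6% of replicated peaks and 9.53% of those placed at random.

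Away from start sites, 6130 of 25038 domains (24.5%) lay over 5000 bp from every annotated TSS, those inside genes included. They were narrower (523 against 1683 bp) and lower in signal (5.48 against 33.1) than the others. The widest spanned 7041 bp of intergenic sequence on chromosome 13 (21166709 to 21173749), 5696 bp from Trim27. The next lay on chromosome 6 (51168251 to 51174861, 6611 bp), 95049 bp from Mir148a, on chromosome 11 (119052888 to 119059066, 6179 bp), 11919 bp from the Polycomb gene Cbx8, on chromosome 15 (85669520 to 85675638, 6119 bp) in an intron of the noncoding gene Lncppara, and on chromosome X (12086501 to 12092304, 5804 bp) in an intron of Bcor. Their signals ranged up to 58.2, at the chromosome 15 domain. The replicates alone gave 7492 and 5214 such domains, and stricter peaks 3088.

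The replicates marked nearly the same genes. Of protein-coding promoters, 14753 were marked in both, 261 in replicate 1 only and 41 in replicate 2 only. Across genes marked in both, Pearson r was 0.921 for log2 signal and 0.937 for log2 width, and Spearman rho 0.836 and 0.945; genes are not independent replicates. The highest promoters of replicate 1 only were those of the surfactant gene Sftpc (signal 48.1), Lmntd2, Gckr, Lor and Rs1. In these 5 cases replicate 2 had a domain 1069 to 1143 bp away, just outside the promoter limit. Over all promoters marked in 1 replicate only, few had a domain of the other replicate within 2500 bp, 27 of 261 (10.3%) in replicate 1 and 8 of 41 (19.5%) in replicate 2, and their median signals were 3.63 and 3.75. The highest promoters of replicate 2 only were those of Bricd5 (signal 34.0), Stap1, Cpsf4l, Hcst and Spns3. Replicate 1 had a domain 1033 bp from the start site of Bricd5 and 1526 bp from that of Hcst. In the replicated list Bricd5 shared its domain with E4f1 and Pgp, and Hcst with Nfkbid.

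Of replicate 1 peaks, 76.6% overlapped a replicate 2 peak, and of replicate 2 peaks 95.3% overlapped a replicate 1 peak, against at most 2.70 and 3.12% at random. The Jaccard index of covered bases was 0.815. The 8209 peaks of replicate 1 only were narrow and weak (238 against 1152 bp for shared peaks, signal 3.39 against 18.2), lay at promoters in 23.3% and in introns in 43.9% of cases, and held 5.78% of that replicate's covered bases. The 1433 peaks of replicate 2 only had 213 bp, a signal of 3.50, 29.5% at promoters and 1.00% of covered bases. With equal numbers of top peaks per replicate, which shortens the list of replicate 1, the peaks without a partner were 4608 in replicate 1 and 2320 in replicate 2. The authors' replicated list kept 91.0% of the pooled peaks. The 2961 not kept were 219 bp wide with low signal, and 0.844% of them overlapped peaks of both replicates, against 86.7% of those kept.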

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

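In this part, the tests with draws matched on the number of annotated TSSs and of the signal in each replicate alone were chosen after the results were seen.

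Peaks were also present in sequence that the comparisons leave out. The replicated list holds 10 peaks on 6 unlocalized or unplaced scaffolds, 7940 bp in all, with a median signal of 8.83 and a highest signal of 43.8 on a scaffold assigned to chromosome X. Replicate 1 had 10 such peaks, replicate 2 had 9 and the pooled list 11. Repeated sequence is common on such scaffolds, and whether these peaks come from unique sequence was not tested.

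The genes of the heart muscle lists carried wider promoter domains than other marked genes, with a median of 5284 bp over 86 genes, 2.58 times that of random draws. The CpG ratio near the start site as the whole cause is argued against by a ratio of 2.80 against draws matched on it. How far CpG-rich sequence extends was not matched, so CpG content over the whole domain was not tested. The number of annotated start sites is argued against by a ratio of 2.57 against draws matched on it. Joining of neighbouring peaks accounts for part of the width, since the ratio was 1.82 with peaks not joined, and not for all of it. Each of these permutation p-values was 2e-05, the smallest the draws can give. A candidate explanation that stays open is the high activity of these genes in heart muscle, but the design has 1 group, expression was not analysed here, and no biological explanation was tested.

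The promoters of Hox genes and neural transcription factors carried low signal, with a median of 11.4 over 57 marked genes, 0.264 times that of random draws. CpG content is argued against by a ratio of 0.251 to CpG-matched draws, and a low signal in 1 replicate only by ratios of 0.265 and 0.276 in replicates 1 and 2. Each permutation p was 2e-05, the smallest the draws can give. Marking in a minority of cells, such as nerve cells of the heart, and low H3K4me3 together with a repressive mark in most cells could both give such values. A second mark and separated cells were not analysed here, so no biological explanation was tested.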

How the results depend on the processing

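In this part, the widths from draws matched on the number of annotated TSSs, the widths with 1 gene per domain and the signals from CpG-matched draws were chosen after the data were seen. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits cannot be given. Where no cause is stated, the cause was not tested.

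Over the lists and settings, direction and side of the threshold were kept in 273 of the tests of width, 228 of those of marked share and 115 of those of signal. With the direction kept, a call was lost in 17, 22 and 13 cases and gained in 6, 13 and 9. The direction turned in 2, 25 and 7 cases. Some of these lost their call as well, such as the cell cycle share with CpG-matched genes. Widths of cardiac transcription factors, sarcomere, calcium and ventricular genes passed in every setting run, with ratios from 1.77 to 4.41.

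Without 1 replicate in turn, the difference in width between atrial and ventricular genes ranged from -3539 to -3305 bp and passed. The threshold of broad domains ranged from 4382 to 4825.6 bp, the promoter share from 57.1 to 64.8%, and the number of lists narrower than other genes from 1 (without replicate 1) to 3. In replicate 2 the skin list had 4 and the olfactory list 3 marked members and neither was tested, so that fall shows no lost narrowness. Values on both sides of 1 were those of neural crest width (0.921 to 1.08), of the signal of cardiac transcription factors (0.947 to 1.07) and of the neural crest share (0.988 to 1.03). In the pooled list the lymphatic share turned to 1.69 and the neural crest share to 0.989.

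With peaks of a −log10 q of 10 or more, which removes weak peaks by construction, replicates 1 and 2 held 21014 and 19260 peaks with medians of 1469 and 1419 bp. Overlap was 87.6 and 99.3%, the Jaccard index 0.843, and 2598 and 144 peaks were in 1 replicate only. The promoter share was 76.1%, 65.8% of protein-coding genes were marked, 3088 domains were distal and 100% of pooled peaks were kept. The shares of Hox (0.821) and neural crest genes (0.750) turned.

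With peaks above the median signal, which removes more, 90.3% lay at promoters, 60.2% of genes were marked, 898 domains were distal and broad domains started at 4286.3 bp. Overlap was 83.9 and 99.8%, with 2823 and 36 peaks in 1 replicate only. In marked share 11 lists were below other genes, and in width 1 list, with the skin and olfactory lists too small to test. The atrial minus ventricular signal turned to 3.90. Shares turned for atrial (0.780), lymphatic (1.19), fibroblast (0.748), neural crest (0.457), neuronal (0.343), neural transcription factor (0.513) and Hox genes (0.299).

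With a flank of 2500 bp, 71.1% of peaks were at promoters and 69.1% of genes marked, by construction more than at 1000 bp. With a flank of 500 bp the neural crest share turned to 0.481. With the most upstream TSS only, 64.4% of genes were marked and the neural crest share turned to 0.553. Broad domains started at 3984.6 bp with peaks not joined and at 6099.3 bp when joined at 3000 bp, where the pancreas width turned to 1.27.

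With genes matched on CpG ratio, 7 lists were above and 3 below other genes in marked share (8 and 5 by the first form of the test). The first form also called ventricular genes above, and hepatocyte and pancreas genes below. Shares turned for conduction (0.144), erythroid (2.43), macrophage (1.98), neural crest (0.794), neuronal (0.990), skin (1.25), neural transcription factor (0.585), Hox (0.403), cell cycle (0.835), ribosomal (0.389) and imprinted genes (0.867). In width 1 list was below other genes. In signal 3 lists were above, and ratios turned for sarcomere (1.83), calcium (1.10), atrial (1.07), ventricular (1.01), smooth muscle (1.09) and skin genes (1.23).

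With equal numbers of peaks, overlap was 84.8 and 92.3%, the Jaccard index 0.830, and 4608 and 2320 peaks were in 1 replicate only. With a reciprocal overlap of 50%, overlap was 68.3 and 79.1%, and 6344 peaks were in replicate 2 only. Peaks wider than 200 bp had medians of 864 and 955 bp. For signal times width, Pearson r was 0.956 and Spearman rho 0.924, and with unmarked promoters at 0 rho was 0.945.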

Other observations

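In this part, the tests of Hox paralogs, of chromosome X in each replicate and for width, and of the downstream share with width-matched draws were chosen after the results were seen, and chromosome X was picked after the values of all chromosomes were seen.

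Sex-linked promoters were seen in these pools of male and female embryos. On chromosome Y, 4 of 183 protein-coding genes were marked, all of them widely expressed genes with a related copy on X. They were the demethylase gene Kdm5d (859 bp, signal 18.8), Uty (1185 bp, 19.8), the translation factor gene Eif2s3y (1431 bp, 16.1) and the helicase gene Ddx3y (1857 bp, 21.1). In replicates 1 and 2 their signals were 18.4 and 14.8 (Kdm5d), 23.5 and 12.1 (Uty), 17.5 and 11.3 (Eif2s3y) and 22.9 and 14.3 (Ddx3y). These genes were chosen after their values were seen, and whether peaks could be called at the other Y genes was not tested. On chromosome X, 507 of 948 genes were marked (53.5%), with a median width of 1820 bp and a median signal of 29.6. The autosomes ranged from 55.4 to 82.4% marked, 1985 to 2187 bp and signals of 41.2 to 46.3.

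Marked promoters on chromosome X had a median signal 0.674 times that of as many autosomal promoters (0.657 and 0.654 in replicates 1 and 2), and their median width ratio was 0.886. CpG content is argued against as the whole cause, since the ratio was 0.786 against CpG-matched draws, yet it accounts for part of the difference. A candidate explanation is the lower number of active X copies, which would lower strong and weak promoters alike. The 95th percentile of signal on X was 0.645 times that of autosomal promoters (0.644 and 0.666 in the replicates), as that hypothesis needs. The draws for this percentile were not CpG-matched, and any cause that lowers all X promoters alike would give such a ratio. The percentile therefore does not tell such causes apart. Each permutation p was 2e-04, the smallest that these draws can give; the sexes were pooled, so copy number was not compared between groups, and the hypothesis stays open.

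Within the Hox clusters, paralogs 1 to 5 carried more signal than paralogs 9 to 13, with medians of 13.9 over 15 genes and 4.46 over 16 genes, unmarked genes at 0. The ratio was 3.12 (two-sided permutation p = 0.00894), and 3.33 (p = 0.00350) and 2.05 (p = 0.0382) in replicates 1 and 2. Of the former 15 of 15 were marked, and of the latter 12 of 16. What gives this order was not tested. Neighbouring Hox genes share domains, so the genes are not independent and the p-values are too small.

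In the median, the domains of the heart muscle lists reached mostly into the transcribed side. A median of 83.0% of the domain lay downstream of the most upstream annotated start site within 1000 bp of the domain, so that sequence between alternative start sites counts as downstream, against 70.0% in random draws of marked genes (permutation p = 2e-05, the smallest possible) and 74.3% in draws matched on width (permutation p = 1e-04). In bases the medians were 4073.5 downstream against 1304, and 833 upstream against 587. Extension along the transcribed gene may thus make up most of the extra width in these medians, as a hypothesis, and the link to transcription was not tested. Single genes can differ. On the minus strand, Nkx2-5 ended at 26845009 and its domain at 26854428, on the upstream side. On the plus strand, Hand2 started at 57320983 and its domain at 57311725. How many other genes have domains that reach as far upstream was not counted.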
